A study of Rattus norvegicus with 20 samples.

How the data were processed

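Frozen kidney samples of rats were measured by stranded, paired-end mRNA sequencing in 20 libraries, per the labels' protocols. Per the submitters' processing notes, read quality was examined with FastQC 0.11.2, Picard 1.119 and SAMtools 1.0, reads were aligned with STAR to the rn6 build, and reads per gene were counted with featureCounts of Subread 1.5.0. Per the same notes the authors normalized the counts with DESeq2, so the deposited signal values are normalized read counts. The table's header names the gene annotation, and the settings of the alignment and counting are not given in the sources used here. Whole reads were recovered from the deposited values by the size factor of each library, with 100% of values within 0.1 read of a whole number. Size factors recomputed from these reads with DESeq2 followed the recovered ones (r = 0.9997 across libraries, on the log scale). Coordinates are those of the file.

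Libraries were put into the groups Sham, RM, HS and RM-HS by their labels, and never by their values. Replicate numbers follow the order in which the samples are listed. The table had 34681 rows, of which 14588 were 0 in every library and 18020 had no gene symbol. Rows with a value of at least 10 in at least 3 libraries were tested, which left 15954, of which 12967 had a symbol. The 14 mitochondrial rows passed the filter and stayed in the tests and in the authors' scaling. With at least 23.3 M other reads per library, counting error was small for most tested genes, and the spread between libraries set the precision.

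The main test was limma 3.58.1 in R 4.3.3, with a mean-variance trend, on log2(value + 1) in 1 fit of the 4 group means over 20 libraries. Contrasts were RM, HS and RM-HS against Sham, RM-HS against RM, RM-HS against HS, RM against HS, and RM-HS minus RM minus HS plus Sham, called the departure from additivity. Genes passed at a Benjamini-Hochberg adjusted p under 0.05 in each contrast. Gene lists written before the data were examined were tested with camera of limma at a preset inter-gene correlation of 0.01, adjusted over the 39 lists that had at least 4 tested members. Of 41 lists, mitochondrially encoded transcripts had 0 of 9 symbols in the file, and sex markers had 3 of 6 tested, so neither was tested. Members were also counted by their adjusted p over all genes and over the list alone. A list is described where camera passed or where at least 1 in 4 members did, and no direction is given for a list without a camera call.

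Genes were named by a rule fixed before the data were examined. The rule took the 6 largest rises and 6 largest falls against Sham, and 4 and 4 otherwise, among genes with an adjusted p under 0.05, a mean of at least 50 in the higher group, a symbol and groups that did not overlap, except that overlap was allowed for additivity. It added Havcr1, Lcn2, Hmox1, Clu and Spp1 in each comparison with Sham, and up to 4 members of each described list by smallest adjusted p, of which the text gives some, and some are not reported here. Genes outside this rule, namely the segment genes described for the Sham libraries, were chosen after their values were seen.

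Alternatives fixed before the data were examined were other pseudocounts (0.5 and 8), no filter, a stricter filter (50 in 3 libraries), scaling by trimmed mean of M values and by upper quartile, fits of only the groups compared, the first letter of the library name (R or S) as covariate, libraries named R alone, array weights, edgeR 4.0.16 and DESeq2 1.42.0 on recovered reads, leaving out each library, an estimated inter-gene correlation, and splits of the Sham libraries. RM has 1 library named R and 5 named S, HS has 3 and 2, and Sham and RM-HS have only R. Controls Sham 1 and Sham 6 alone, and the podocyte list mean as a covariate, were added after seeing the data. That covariate is the mean of the tested podocyte list genes. With it, the loss of that list and of its members was largely fixed in advance and says nothing about them.

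The procedure was tested on simulations with 100 genes changed per size and comparison. A 2-fold change was recovered in 66%, 64%, 45%, 63%, 61%, 54% and 28% of genes for the contrasts in the order above. A 0.5 log2 change was recovered in 19%, 21%, 8%, 11%, 10%, 20% and 0%. Far more genes passed in most contrasts, so recovery there may differ.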

Results

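The series concerns acute kidney injury after trauma in rats, and its design text asks which transcriptional programmes go with that injury. RNA was extracted from frozen kidney samples of rats and sequenced as stranded, paired-end mRNA libraries. The labels put 20 libraries into 4 groups, which were 6 libraries of Sham, 6 of RM, 5 of HS and 3 of RM-HS, and they do not spell out RM or HS. The design text counts 19 libraries with 5 in RM, whereas the labels give 6 RM libraries, and all 6 were used. No source says that each library came from a separate animal, so the p-values measure only the spread between these samples, which may be partly technical. Each library held between 45047179 and 109940948 reads in the table. Of these 42.2% to 54.7% lay on 14 rows of the mitochondrial genome, leaving 23.3 to 51.9 M other reads. Of 34681 rows, 15954 passed the filter on low values and were tested. All fold changes are on the log2(value + 1) scale, which understates the change of low genes, and are given as log2 fold change ± SE. Levels are DESeq2-normalized read counts, given as mean ± SD over the libraries of a group. Largest rises and falls are those among genes that met the naming rule.

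The Sham libraries differed among themselves in nephron segment markers. Slc5a2, the glucose transporter of the early proximal tubule, stood at 6790 in Sham 1 and 7860 in Sham 6, but at 48.2, 396, 180 and 43.1 in Sham 2, 3, 4 and 5, against 9390 or more in every RM, HS and RM-HS library. Relative to the mean of the RM, HS and RM-HS libraries, the median of 7 early proximal tubule genes was -0.40 and -0.68 (log2) in Sham 1 and 6, and -5.29, -3.85, -4.11 and -5.12 in Sham 2, 3, 4 and 5. The podocyte median was -0.07 and -0.03 in Sham 1 and 6, and -2.06, -0.68, -1.25 and -1.95 in Sham 2 to 5. The distal convoluted tubule median split Sham 2 to 5, at -2.10, 0.81, 0.98 and -0.89. The late proximal tubule genes went both ways, with a median over Slc7a13, Slc5a1 and Slc22a7 of 0.67, 0.48, 0.58 and 1.04 in Sham 2 to 5 and 0.24 and 0.25 in Sham 1 and 6. Slc5a1 itself was lower in every Sham library (469 to 966) than in every RM, HS and RM-HS library (1060 or more). For this reason gene counts against Sham are given with all 6 controls and again with Sham 1 and Sham 6 alone, and list and gene results where that ended or made a call, a choice made after seeing these values and resting on them.

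**Figure D1:**
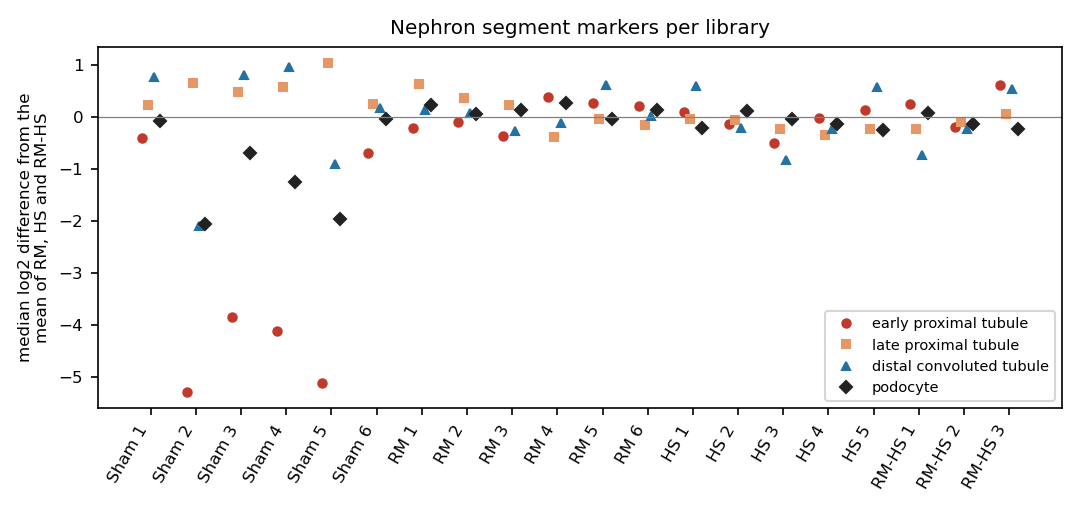
Median log2 difference of nephron segment marker genes (y axis) from the mean of the RM, HS and RM-HS libraries, in each of the 20 libraries (x axis), with 1 point per library and segment. Sham 2, 3, 4 and 5 lie between -5.29 and -3.85 in the early proximal tubule genes, and Sham 1 and Sham 6 at -0.40 and -0.68.

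RM against Sham asked what changed in the kidney with RM alone. The largest rises were in Slc7a11, the cystine importer that feeds glutathione synthesis (GSRG0016319, rn6 chromosome 2, 139453774 to 139528162), and in Hmox1, haem oxygenase 1, which breaks down haem (GSRG0037266, rn6 chromosome 19, 14508634 to 14515453). Slc7a11 went from 17.5 ± 12.6 in Sham (n = 6) to 5760 ± 3110 in RM (n = 6), a log2 fold change of 8.26 ± 0.61 (limma adjusted p = 3.4e-09). Hmox1 went from 2520 ± 5090 to 157000 ± 24100, a change of 7.64 ± 0.72 (limma adjusted p = 7.3e-08). With them rose the AP-1 subunit Fosl1 (6.89 ± 0.48), the secreted neuroendocrine peptide precursor Vgf (7.04 ± 0.58), Lypd8 (7.69 ± 0.73) and Lexm (7.60 ± 0.46). The largest falls were in Smim5 (-5.40 ± 0.64), the BMP-pathway factor Smad9 (-4.94 ± 0.76), the adaptor Dok7 (-4.81 ± 0.41), the histamine receptor Hrh3 (-4.54 ± 0.61), Tril (-4.48 ± 0.47) and Rd3l. Rd3l had 3 reads in all over the RM libraries, and its level in Sham was 114 times that in RM (counting interval 39 to 553), and all 3 reads were in RM 3. In each of these 12 genes every RM library lay beyond every Sham library. Over all genes 8455 of 15954 passed, 4178 higher and 4277 lower, and 3157 of them changed by 2-fold or more.

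Kidney injury markers moved together in RM. Of 19 tubular injury markers 14 rose and 5 did not pass, the same number when adjusted over the list alone (camera adjusted p = 2.0e-05, and adjusted p = 0.3 with an estimated correlation). Havcr1, kidney injury molecule 1 (GSRG0005308, rn6 chromosome 10, 31814245 to 31846857), rose from 151 ± 98.8 to 5170 ± 3320 (5.01 ± 0.58), Gdf15, a stress cytokine, by 4.10 ± 0.28, the integrin Itgb6 by 1.29 ± 0.10, the chaperone Clu by 1.64 ± 0.26, and Spp1, osteopontin, by 1.10 ± 0.38 (limma adjusted p = 0.021). The Spp1 call rested on single libraries, with limma adjusted p = 0.056 without Sham 6 and 0.061 without RM 3, and was lost with the name letter (0.13) or the podocyte list mean (0.061) as covariate. Lcn2, neutrophil gelatinase-associated lipocalin (GSRG0020272, rn6 chromosome 3, 11414189 to 11417596), had 1730 ± 1880 in Sham and 5670 ± 6920 in RM and did not pass (2.13 ± 1.31, limma adjusted p = 0.18). With Sham 1 and Sham 6 alone as controls it did (5.01, limma adjusted p = 0.021).

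Stress and signalling genes rose in RM. Counts adjusted over the list alone were the same in this paragraph unless given. Of the 15 immediate early genes 14 rose (camera adjusted p = 1.8e-09, and adjusted p = 0.27 with an estimated correlation), among them the transcription factors Atf3 (6.24 ± 0.31) and Myc (4.22 ± 0.21). In the NRF2 antioxidant list 10 of 14 rose (camera adjusted p = 0.00013, and adjusted p = 0.3 with an estimated correlation). Among them were Srxn1, sulfiredoxin, at 5.51 ± 0.28 and Txnrd1, thioredoxin reductase, at 2.88 ± 0.18. The unfolded protein and integrated stress response list had 12 of 17 higher, or 15 adjusted over the list alone (camera adjusted p = 2.0e-05, and adjusted p = 0.3 with an estimated correlation), including Atf4 (2.12 ± 0.14) and the chaperone partner Dnajb9 (2.29 ± 0.19). Heat shock genes rose in 9 of 10 (camera adjusted p = 0.0029, and adjusted p = 0.49 with an estimated correlation), such as Hsp90aa1 (2.31 ± 0.28) and Hspa8 (1.43 ± 0.16). Of the p53 targets 8 rose and 2 fell of 12 (camera adjusted p = 0.029, and adjusted p = 0.3 with an estimated correlation). Members included the cell cycle inhibitor Cdkn1a at 2.99 ± 0.27 and Mdm2 at 1.31 ± 0.14. Among 11 ferroptosis genes 7 rose, or 8 adjusted over the list alone, and 1 fell (camera adjusted p = 0.01, and adjusted p = 0.14 with an estimated correlation), and the lipid-activating enzyme Acsl4 was among the rises (1.30 ± 0.12).

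Metabolic and inflammatory lists also passed in RM, with counts adjusted over the list alone equal to those given. Cholesterol synthesis rose in 10 of 13 genes (camera adjusted p = 3.2e-06, and adjusted p = 0.14 with an estimated correlation). An example was Insig1, a regulator of sterol synthesis, at 2.58 ± 0.11. Glycolysis genes rose in 8 and fell in 1 of 14 (camera adjusted p = 0.0056, and adjusted p = 0.27 with an estimated correlation). Among them were Hk2, a hexokinase, at 2.47 ± 0.26 and Gpi at 0.90 ± 0.08. In the hypoxia list 9 rose and 3 fell of 16 (camera adjusted p = 0.011, and adjusted p = 0.3 with an estimated correlation). Members included the vasodilator peptide Adm at 3.22 ± 0.20 and Pfkfb3, an activator of glycolysis, at 2.56 ± 0.17. All 9 tested neutrophil markers rose (camera adjusted p = 0.00056, and adjusted p = 0.3 with an estimated correlation), including the chemokine receptor Cxcr2 (2.97 ± 0.39). Of 17 inflammatory cytokines and NF-kB targets 14 rose (camera adjusted p = 0.00015, and adjusted p = 0.35 with an estimated correlation), such as the chemokine Ccl20 (5.29 ± 0.50) and the NF-kB inhibitor Nfkbia (1.27 ± 0.13). Vasoactive genes rose in 8 of 13 (camera adjusted p = 0.047, and adjusted p = 0.3 with an estimated correlation). Examples were the endothelin receptor Ednra at 1.94 ± 0.21 and the bradykinin receptor Bdkrb2 at 1.95 ± 0.28.

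Nephron segments moved in different directions in RM. All 10 collecting duct principal cell genes fell, also adjusted over the list alone (camera adjusted p = 0.00038, and adjusted p = 0.3 with an estimated correlation), such as the vasopressin receptor Avpr2 (-3.57 ± 0.42) and Hsd11b2, which inactivates glucocorticoids (-1.90 ± 0.22). Against Sham 1 and Sham 6 alone 4 of the 10 fell (camera adjusted p = 0.0056). Thick ascending limb genes fell in 8 of 10, or 9 adjusted over the list alone (camera adjusted p = 0.0057, and adjusted p = 0.37 with an estimated correlation), including the chloride channel subunit Bsnd (-2.54 ± 0.37) and the potassium channel Kcnj1 (-1.34 ± 0.21). Proximal tubule genes rose in 12, or 13 adjusted over the list alone, and fell in 3 of 18 (camera adjusted p = 0.022, and adjusted p = 0.53 with an estimated correlation). Among them were Slc5a1 at 0.91 ± 0.16 and the phosphate transporter Slc34a1 at 1.0 ± 0.19. All 8 podocyte genes rose, also adjusted over the list alone (camera adjusted p = 0.0073, and adjusted p = 0.49 with an estimated correlation), including the slit diaphragm protein Nphs1 (2.16 ± 0.43). These last lists moved with the low Sham libraries, and with Sham 1 and Sham 6 alone 3 proximal tubule genes and 1 podocyte gene rose and neither list passed (camera adjusted p = 0.36 and 0.26). Slc34a1 did not pass with those controls either (0.37, limma adjusted p = 0.088), nor with the podocyte list mean as covariate (limma adjusted p = 0.14). Nphs1 did not pass with that covariate (limma adjusted p = 0.15), but it is itself part of it. The median log2 fold change of the 7 early proximal tubule genes was 3.18 with all controls and 0.35 with Sham 1 and Sham 6.

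In the other lists of which at least 1 in 4 members passed, the camera test did not. Interferon response genes fell in 9 and rose in 1 of 15 (camera adjusted p = 0.063). Glucocorticoid response and metallothionein genes rose in 7 and fell in 1 of 10 (camera adjusted p = 0.053). The haem and iron list had 8 rises and 3 falls of 18, or 4 falls adjusted over the list alone (camera adjusted p = 0.2). Circadian clock genes had 6 rises and 3 falls of 15, cell cycle genes 3 and 6 of 17, fatty acid oxidation 1 and 5 of 19, endothelial genes 2 and 3 of 9, complement and acute phase 3 and 3 of 13, and osmotic response 3 and 1 of 7 (camera adjusted p = 0.16, 0.29, 0.2, 0.71, 0.52 and 0.22). Adjusted over the list alone, clock genes had 7 rises, and falls were 3 in fatty acid oxidation, 4 in endothelial and 4 in fibroblast and matrix genes. Macrophage genes rose in 3 of 12 and regulated necrosis genes in 3 of 11, while fibroblast and matrix genes fell in 5 of 13 and intercalated cell genes in 4 of 9 (camera adjusted p = 0.25, 0.2, 0.44 and 0.12). Of small lists, T and NK cell genes had 1 rise and 2 falls of 10, or 1 fall and no rise adjusted over the list alone. Adrenal and adipose genes each had 1 rise and 1 fall of 4, the distal convoluted tubule 1 rise of 4 and liver 2 of 7 (camera adjusted p = 0.71, 0.64, 0.71, 0.5 and 0.2). The number of genes passing was 5250 with Sham 1 and Sham 6 alone, 4835 of them the same genes in the same direction. Of 17 lists with a camera call 15 kept it with these controls, and 15 with the podocyte list mean as covariate. There the proximal tubule list did not pass (camera adjusted p = 0.46). Nor did the podocyte list, a loss fixed in advance because its own genes make up the covariate. The count of genes was 4551 with the letter of the library name as a covariate and 782 among libraries named R, where RM 1 is the only RM library and the other groups supply the spread. Of the genes named for RM, those that did not pass among libraries named R were Rd3l, Smad9, Tril, Havcr1, Clu, Spp1, Slc5a1, Slc34a1, Bsnd, Kcnj1, Hsd11b2, Nphs1, Cxcr2 and Mdm2, besides Lcn2. Under upper quartile scaling, which moved the median of all genes by -0.11 log2, 3443 genes were higher and 5204 lower.

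HS against Sham asked the same of HS alone. The largest rise was in Havcr1, from 151 ± 98.8 in Sham to 14600 ± 9640 in HS (n = 5), a log2 fold change of 6.63 ± 0.61 (limma adjusted p = 2.0e-07). Krt20, a keratin (GSRG0006812, rn6 chromosome 10, 87342502 to 87351063), went from 7.09 ± 7.19 to 502 ± 312 (6.43 ± 0.67), and in RM it stood at 1.85 ± 1.73. The fibrinogen chains Fgb (6.18 ± 0.67) and Fgg (5.50 ± 0.73), the cytochrome Cyp3a9 (5.61 ± 0.74) and Lypd8 (6.43 ± 0.77) made up the other largest rises. The largest falls were in the urea transporter gene Slc14a2 (-4.87 ± 1.60), Smim5 (-4.84 ± 0.67), the cytochrome Cyp1a1 (-4.80 ± 0.72), Lrtm2 (-4.45 ± 0.78), Synpo2l (-4.33 ± 0.55) and Tnni3k (-4.27 ± 0.99). By the naming rule, every HS library lay beyond every Sham library in these 12 genes. Slc14a2 did not pass without HS 1 (-4.11, limma adjusted p = 0.053) or with Sham 1 and Sham 6 alone (-4.83, limma adjusted p = 0.15), nor with the name letter (0.072) or the podocyte list mean (0.056) as covariate. In all 7410 genes passed, 3712 higher and 3698 lower, and 2269 changed by 2-fold or more.

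Of the injury markers 14 of 19 rose in HS, or 15 adjusted over the list alone (camera adjusted p = 7.9e-05, and adjusted p = 0.57 with an estimated correlation). Members included Itgb6 at 1.14 ± 0.10 and Clu at 1.11 ± 0.27. Hmox1 rose by 2.87 ± 0.76 to 10200 ± 14500 (limma adjusted p = 0.0041), but HS 2 (36000, others 2470 to 4970) and Sham 6 (12900, others 400 to 500) weighed on these means. It did not pass with Sham 1 and Sham 6 alone (1.28, limma adjusted p = 0.37), with the podocyte list mean as covariate (1.67, limma adjusted p = 0.14), or by edgeR (2.07, adjusted p = 0.07) or DESeq2 (2.02, adjusted p = 0.08). Lcn2 (3.09 ± 1.37, limma adjusted p = 0.072) and Spp1 (0.83 ± 0.40, limma adjusted p = 0.097) did not pass. Both passed without HS 1 (limma adjusted p = 0.019 and 0.04), and Lcn2 also without Sham 2 (0.036), without Sham 3 (0.044) or with Sham 1 and Sham 6 alone (0.012). The unfolded protein and integrated stress list rose in 10 of 17, the same number adjusted over the list alone (camera adjusted p = 0.0024, and adjusted p = 0.57 with an estimated correlation), including Dnajb9 (1.56 ± 0.19) and Vldlr (1.04 ± 0.13). Immediate early genes rose in 8 of 15, as they did adjusted over the list alone (camera adjusted p = 0.0039, and adjusted p = 0.74 with an estimated correlation), such as Klf6 (2.38 ± 0.24) and Myc (2.23 ± 0.22). Among p53 targets 6 rose and 1 fell of 12, as adjusted over the list alone (camera adjusted p = 0.016, and adjusted p = 0.57 with an estimated correlation). Examples were Tp53inp1 at 2.57 ± 0.24 and Sesn2 at 1.55 ± 0.17.

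Further lists passed in HS, with the same counts adjusted over the list alone unless given. Ferroptosis genes rose in 8 and fell in 1 of 11 (camera adjusted p = 0.016, and adjusted p = 0.31 with an estimated correlation). Among them were Acsl4 at 1.60 ± 0.13 and the polyamine enzyme Sat1 at 1.29 ± 0.20. Glucocorticoid response and metallothionein genes rose in 7 and fell in 1 of 10 (camera adjusted p = 0.015, and adjusted p = 0.57 with an estimated correlation). Members included the pyruvate dehydrogenase kinase Pdk4 at 2.39 ± 0.24 and Klf9 at 1.05 ± 0.19. Heat shock genes rose in 6 of 10, or 7 adjusted over the list alone (camera adjusted p = 0.037, and adjusted p = 0.8 with an estimated correlation). Examples were Hsp90aa1 at 1.76 ± 0.30 and Hspa1b at 3.38 ± 0.77. Hspa1b has a near-identical copy, so its share of reads is uncertain. Cholesterol synthesis rose in 8 and fell in 1 of 13 (camera adjusted p = 0.045, and adjusted p = 0.66 with an estimated correlation). Among them was Insig1 at 1.0 ± 0.12. Nuclear genes of oxidative phosphorylation fell in 11 of 19 (camera adjusted p = 0.0045, and adjusted p = 0.74 with an estimated correlation). Members included the complex I subunits Ndufv1 at -0.47 ± 0.07 and Ndufa9 at -0.35 ± 0.07. Interferon response genes fell in 8 and rose in 1 of 15 (camera adjusted p = 0.041, and adjusted p = 0.82 with an estimated correlation). Examples were the ISG15 protease Usp18 at -1.87 ± 0.38 and Ifi27 at -1.40 ± 0.24. The interferon list did not pass with Sham 1 and Sham 6 alone (camera adjusted p = 0.066) or with the name letter as covariate (0.067).

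Lists of the thick ascending limb, principal cells and intercalated cells were lower in HS. Thick ascending limb genes fell in 9 of 10, also adjusted over the list alone (camera adjusted p = 0.00087, and adjusted p = 0.57 with an estimated correlation). Among them were the claudin Cldn10 at -1.53 ± 0.14 and Kcnj1 at -1.40 ± 0.22. Collecting duct principal cell genes fell in 9 of 10, or 10 adjusted over the list alone (camera adjusted p = 0.0024, and adjusted p = 0.57 with an estimated correlation). Members included Hsd11b2 at -1.39 ± 0.23 and the water channel Aqp3 at -1.38 ± 0.25. Intercalated cell genes fell in 8 of 9, also adjusted over the list alone (camera adjusted p = 0.0024, and adjusted p = 0.57 with an estimated correlation). Examples were the proton pump subunit Atp6v1b1 at -1.64 ± 0.22 and the anion exchanger Slc4a1 at -1.95 ± 0.26. Falls in these lists numbered 7, 2 and 4 with Sham 1 and Sham 6 as the only controls (camera adjusted p = 0.00039, 0.028 and 0.043). Podocyte genes rose in 5 of 8, or 6 adjusted over the list alone (camera adjusted p = 0.045, and adjusted p = 0.8 with an estimated correlation). Among them were Wt1 at 1.35 ± 0.35 and Nphs1 at 1.73 ± 0.45. That list moved with the low Sham libraries and did not pass with Sham 1 and Sham 6 alone (camera adjusted p = 0.79), nor did Wt1 (0.24, limma adjusted p = 0.43) and Nphs1 (0.22, limma adjusted p = 0.25). The median of the 7 early proximal tubule genes was 3.16 with all controls and 0.49 with those 2, and the proximal tubule list, with 10 rises and 3 falls of 18, passed with neither (camera adjusted p = 0.11 and 0.97).

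The remaining lists with at least 1 in 4 members passing had no camera call in HS. Rises and falls were 5 and 5 of 14 for NRF2 genes, 6 and 5 of 18 for haem and iron, 7 and 4 of 16 for hypoxia, 5 and 3 of 14 for glycolysis and 2 and 4 of 17 for inflammatory cytokines and NF-kB targets (camera adjusted p = 0.93, 0.9, 0.3, 0.87 and 0.9). They were 2 and 6 of 9 for endothelial genes, 4 and 4 of 11 for regulated necrosis, 2 and 4 of 19 for fatty acid oxidation, 4 and 2 of 7 for osmotic response, 1 and 3 of 12 for macrophages, 3 and 5 of 15 for the circadian clock and 3 and 2 of 13 for vasoactive genes (camera adjusted p = 0.077, 0.87, 0.63, 0.15, 0.58, 0.95 and 0.86). Adjusted over the list alone, rises and falls of the proximal tubule were 11 and 4, and falls were 3 among inflammatory and 6 among clock genes. Fibroblast and matrix genes had 4 falls of 13, and complement and acute phase genes 2 rises and 2 falls of 13. Of small lists, the adrenal gland had 1 rise and 1 fall and adipose tissue 1 rise and 2 falls of 4 each, the distal convoluted tubule 1 rise of 4 and liver 2 of 7 (camera adjusted p = 0.35, 0.87, 0.93, 0.58, 0.57 and 0.3 for these lists). Against Sham 1 and Sham 6 alone 4105 genes passed, 3710 of them the same genes in the same direction, and 12 of 14 lists kept their camera call. With the podocyte list mean as covariate 11 of 14 did, and cholesterol synthesis and interferon lists did not pass (camera adjusted p = 0.06 and 0.1). Nor did the podocyte list (camera adjusted p = 0.9), whose own genes make up that covariate. Besides Lcn2 and Spp1, the genes named for HS that did not pass among libraries named R were Wt1 and Nphs1. Both genes are part of that covariate and did not pass with it, whereas Lcn2 did (4.59, limma adjusted p = 0.039). Upper quartile scaling, with a shift of -0.10 log2 in the median, gave 3055 higher and 4504 lower.

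RM-HS against Sham asked what changed with both labels together. The largest rises were Lypd8 (8.20 ± 0.90), Fosl1 (7.0 ± 0.58), Slc7a11 (6.76 ± 0.75), Hmox1 (6.70 ± 0.88), the AP-1 subunit Fosb (6.42 ± 0.71) and Atf3 (6.28 ± 0.38). Slc7a11 stood at 1680 ± 678 and Hmox1 at 92100 ± 48600 in RM-HS (n = 3). The largest falls were the cardiac kinase gene Tnni3k (-6.22 ± 1.16), Synpo2l (-5.67 ± 0.64), Smad9 (-5.54 ± 0.93), Smim5 (-5.53 ± 0.79), the serotonin receptor Htr5b (-5.49 ± 0.90) and the endothelin Edn3. Edn3 had 2 reads in all over the RM-HS libraries, and its level in Sham was 86.5 times that in RM-HS (counting interval 24 to 714), and both reads were in RM-HS 1. No RM-HS library overlapped a Sham library in these 12 genes. In all 6749 genes passed, 3395 higher and 3354 lower, and 2912 changed by 2-fold or more.

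Injury markers rose in 15 of 19 in RM-HS, or 16 adjusted over the list alone (camera adjusted p = 7.1e-07, and adjusted p = 0.29 with an estimated correlation). Havcr1 rose to 8140 ± 2600 (6.03 ± 0.71), Gdf15 by 4.36 ± 0.34 and Itgb6 by 1.24 ± 0.12. Lcn2 rose to 20400 ± 10200 (5.18 ± 1.60, limma adjusted p = 0.014), a call lost without RM-HS 1 (4.88, limma adjusted p = 0.057). Clu rose by 1.07 ± 0.32, a call lost without RM-HS 2 (0.72, limma adjusted p = 0.11). Spp1 did not pass (1.16 ± 0.47, limma adjusted p = 0.054). It passed in 8 alternatives, including edgeR, DESeq2, Sham 1 and Sham 6 alone, and without RM-HS 3 (0.024). Immediate early genes rose in 14 of 15, also adjusted over the list alone (camera adjusted p = 1.2e-09, and adjusted p = 0.18 with an estimated correlation). Members included Klf6 at 4.24 ± 0.28. The unfolded protein and integrated stress list rose in 10 of 17, also adjusted over the list alone (camera adjusted p = 0.00011, and adjusted p = 0.29 with an estimated correlation). Examples were Atf4 at 2.15 ± 0.18 and Dnajb9 at 2.10 ± 0.23. NRF2 genes rose in 7 and fell in 2 of 14, as adjusted over the list alone (camera adjusted p = 0.039, and adjusted p = 0.61 with an estimated correlation). Among them were Srxn1 at 4.75 ± 0.34 and Txnrd1 at 2.42 ± 0.22.

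Glycolysis genes rose in 10 of 14 in RM-HS, or 11 adjusted over the list alone (camera adjusted p = 0.00015, and adjusted p = 0.1 with an estimated correlation). Members included Eno1 at 0.95 ± 0.10 and Gapdh at 1.0 ± 0.11. Cholesterol synthesis rose in 10 of 13, with 1 fall adjusted over the list alone (camera adjusted p = 8.3e-05, and adjusted p = 0.16 with an estimated correlation), and Insig1 stood at 2.26 ± 0.14. All 9 neutrophil markers rose, also adjusted over the list alone (camera adjusted p = 0.00033, and adjusted p = 0.29 with an estimated correlation). Examples were Cxcr2 at 3.05 ± 0.48 and Retnlg at 3.18 ± 0.65. Inflammatory cytokines and NF-kB targets rose in 12 of 17, also adjusted over the list alone (camera adjusted p = 0.00047, and adjusted p = 0.41 with an estimated correlation). Among them were Ccl20 at 5.0 ± 0.61 and Nfkbia at 1.54 ± 0.16. Hypoxia genes rose in 10 and fell in 3 of 16, as adjusted over the list alone (camera adjusted p = 0.0026, and adjusted p = 0.18 with an estimated correlation). Members included Adm at 3.07 ± 0.25 and Pfkfb3 at 2.73 ± 0.21. Ferroptosis genes rose in 5 of 11, also adjusted over the list alone (camera adjusted p = 0.0049, and adjusted p = 0.1 with an estimated correlation). An example was Acsl4 at 1.48 ± 0.15. Of the p53 targets 7 rose, or 8 adjusted over the list alone, and 1 fell of 12 (camera adjusted p = 0.0049, and adjusted p = 0.19 with an estimated correlation). Among them were Cdkn1a at 3.24 ± 0.33 and Mdm2 at 1.44 ± 0.17. Heat shock genes rose in 6 of 10, or 9 adjusted over the list alone (camera adjusted p = 0.0074, and adjusted p = 0.59 with an estimated correlation). Members included Hsp90aa1 at 1.84 ± 0.35 and Hspa8 at 1.07 ± 0.20. Glucocorticoid response and metallothionein genes rose in 7 and fell in 1 of 10, as adjusted over the list alone (camera adjusted p = 0.03, and adjusted p = 0.41 with an estimated correlation). Examples were the metallothionein Mt2A at 1.79 ± 0.29 and Cebpd at 1.76 ± 0.32.

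All 10 collecting duct principal cell genes fell in RM-HS, also adjusted over the list alone (camera adjusted p = 0.00028, and adjusted p = 0.29 with an estimated correlation). Among them were Avpr2 at -4.12 ± 0.51 and the water channel Aqp2 (GSRG0028276, rn6 chromosome 7, 141237785 to 141242837) at -2.56 ± 0.41. Thick ascending limb genes fell in 6 of 10, or 7 adjusted over the list alone (camera adjusted p = 0.013, and adjusted p = 0.46 with an estimated correlation). Members included Bsnd at -2.93 ± 0.45 and Kcnj1 at -1.35 ± 0.25. When Sham 1 and Sham 6 were the controls, 4 and 5 genes of these lists fell (camera adjusted p = 0.0055 and 0.021). Proximal tubule genes rose in 12, or 13 adjusted over the list alone, and fell in 2 of 18 (camera adjusted p = 0.0074, and adjusted p = 0.55 with an estimated correlation). Examples were the inositol oxygenase Miox at 0.83 ± 0.14 and Slc34a1 at 1.19 ± 0.24. This list moved with the low Sham libraries, with 4 rises and no call with Sham 1 and Sham 6 alone (camera adjusted p = 0.081), and the early proximal tubule median went from 3.20 to 0.61. Podocyte genes rose in 3 of 8, or 4 adjusted over the list alone, without a camera call (adjusted p = 0.055, and 0.67 with Sham 1 and Sham 6).

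Other lists with at least 1 in 4 members passing had no camera call in RM-HS. Interferon response genes rose in 2 and fell in 8 of 15, vasoactive genes rose in 7 and fell in 1 of 13, haem and iron genes rose in 7 and fell in 1 of 18, and clock genes rose in 8 and fell in 3 of 15 (camera adjusted p = 0.16, 0.05, 0.079 and 0.16). Intercalated cell genes fell in 5 of 9, fibroblast and matrix genes in 4 of 13, endothelial genes in 4 of 9 with 2 rises, and cell cycle genes in 4 of 17 with 1 rise (camera adjusted p = 0.072, 0.083, 0.16 and 0.079). Adjusted over the list alone, cell cycle falls were 2 and endothelial falls 5. Macrophage genes rose in 4 and fell in 2 of 12, osmotic response genes in 3 and 2 of 7, and fatty acid oxidation genes in 3 and 3 of 19 (camera adjusted p = 0.5, 0.67 and 0.74). Complement and acute phase genes rose in 3 and fell in 2 of 13, or 4 and 3 adjusted over the list alone, and regulated necrosis genes rose in 3 of 11 (camera adjusted p = 0.44 and 0.55). The distal convoluted tubule and adrenal lists had 1 rise of 4 each, adipose tissue 1 rise and 1 fall of 4, and liver 2 rises of 7 (camera adjusted p = 0.62, 0.74, 0.55 and 0.16). Against Sham 1 and Sham 6 alone 4347 genes passed, 3892 of them the same genes in the same direction, and 15 of 16 lists kept their camera call. Upper quartile scaling, with a shift of -0.11 log2, gave 2722 higher and 4193 lower.

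**Figure D2:**
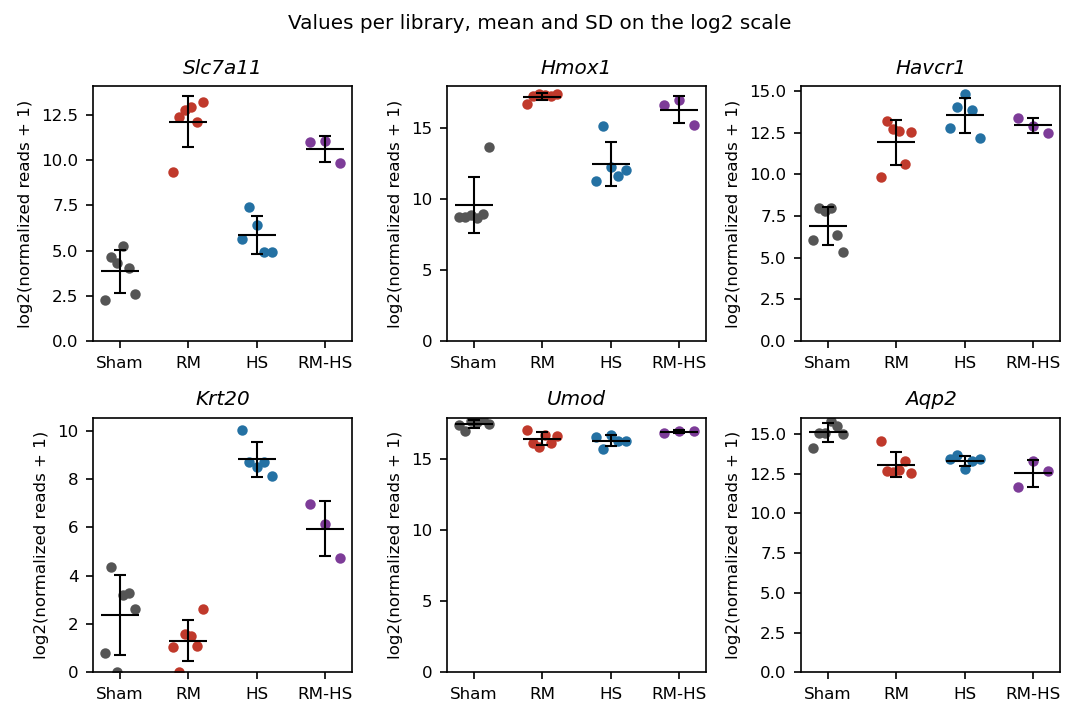
Normalized read counts of 6 genes as log2(value + 1) on the y axis, with 1 point per library in each group on the x axis, and the mean and SD of the log2 values as bars. Hmox1 and Slc7a11 are highest in RM and RM-HS, Krt20 in HS, and Aqp2 lies at 37100 ± 13600 in Sham against 9840 ± 7050, 10300 ± 2100 and 6610 ± 3540 in RM, HS and RM-HS (mean ± SD of the values).

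The comparisons with Sham shared many genes. RM and HS had 5500 passing genes in common, 2822 higher in both, 2571 lower in both and 107 in opposite directions, where independent lists would share 972, 991 and 1964. RM and RM-HS shared 5696 genes, 2964 higher, 2731 lower and 1 opposite (independent lists 889, 899 and 1788). HS and RM-HS shared 4413, with 2322 higher, 2000 lower and 91 opposite (independent lists 790, 777 and 1567). Across genes, which are not independent replicates, the log2 fold changes had r = 0.759, 0.859 and 0.734 and covariances of 0.738, 1.03 and 0.748. Simulated unchanged groups sharing a simulated Sham group gave r = 0.479, 0.405 and 0.386 and a covariance of 0.0761, 0.0760 and 0.0756. With the 6 Sham libraries split 3 and 3, the medians over 20 splits were 3904, 4182.5 and 3178.5 shared genes, with r = 0.624, 0.738 and 0.604. All splits leave some of Sham 2 to 5 in both parts, and the simulation lacked them, so neither removes their part.

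RM against HS asked where the single labels differed. Slc7a11 was 6.26 ± 0.64 higher in RM (limma adjusted p = 1.6e-06), as were the matrix metalloproteinase Mmp10 (5.72 ± 0.79) and Spata48 (5.17 ± 0.93). Slc10a4 averaged 68.8 ± 23.2 in RM and had no read in any of the 5 HS libraries, which makes it at least 14.3-fold higher in RM against a floor of 3 reads per library. Krt20 was lower in RM (-7.50 ± 0.67, limma adjusted p = 4.0e-07), as were Cyp3a9 (-5.30 ± 0.74), the claudin Cldn22 (-3.88 ± 0.64) and the serpin Serpinb5 (-3.39 ± 0.61). Every RM library lay beyond every HS library in these 8 genes. In all 3791 genes passed, 1776 higher in RM and 2015 lower, and 903 differed by 2-fold or more. The count was 208 among libraries named R, where RM has 1 library, and of the genes named here and below the ones that passed there were Krt20, Cyp3a9, Gpi, Hk2, Insig1, Sele, Nfkbia, Zfp36, Atf3 and Bdkrb2.

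Immediate early genes were higher in RM than in HS in 14 of 15, or all 15 adjusted over the list alone (camera adjusted p = 6.7e-12, and adjusted p = 0.13 with an estimated correlation). Among them were Atf3 at 3.24 ± 0.33 and the mRNA decay factor Zfp36 at 2.18 ± 0.17. NRF2 genes were higher in 11 of 14, or 13 adjusted over the list alone (camera adjusted p = 1.7e-09, and adjusted p = 0.13 with an estimated correlation). Members included Srxn1 at 2.66 ± 0.29. Inflammatory cytokines and NF-kB targets were higher in 13 of 17, or 15 adjusted over the list alone (camera adjusted p = 2.3e-09, and adjusted p = 0.18 with an estimated correlation). Examples were E-selectin, Sele, at 4.43 ± 0.49 and Nfkbia at 1.18 ± 0.13. Cholesterol synthesis was higher in 8 of 13, or 11 adjusted over the list alone (camera adjusted p = 8.0e-09, and adjusted p = 0.057 with an estimated correlation). Among them was Insig1 at 1.58 ± 0.12. Glycolysis genes were higher in 9 and lower in 1 of 14, or 10 and 1 adjusted over the list alone (camera adjusted p = 0.00019, and adjusted p = 0.11 with an estimated correlation). Members included Hk2 at 2.49 ± 0.27 and Gpi at 1.19 ± 0.08. Oxidative phosphorylation genes were higher in 5 of 19, or 14 adjusted over the list alone (camera adjusted p = 0.00045, and adjusted p = 0.45 with an estimated correlation). An example was Sdhb at 0.26 ± 0.07. The unfolded protein and integrated stress list was higher in 6 of 17, also adjusted over the list alone (camera adjusted p = 0.0096, and adjusted p = 0.45 with an estimated correlation). Among them were Ddit3 at 1.62 ± 0.23 and Atf4 at 1.20 ± 0.15. Vasoactive genes were higher in 5 of 13, or 6 adjusted over the list alone (camera adjusted p = 0.014, and adjusted p = 0.26 with an estimated correlation). Members included Bdkrb2 at 1.61 ± 0.29.

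Cell type markers differed as well. Neutrophil genes were higher in RM in 7 of 9, or 8 adjusted over the list alone (camera adjusted p = 0.00081, and adjusted p = 0.36 with an estimated correlation). Examples were the collagenase Mmp8 at 2.11 ± 0.52 and Cxcr2 at 1.74 ± 0.41. Macrophage genes were higher in 6 of 12, or 7 adjusted over the list alone (camera adjusted p = 0.0066, and adjusted p = 0.45 with an estimated correlation). Among them were Csf1r at 0.59 ± 0.17 and Adgre1 at 1.05 ± 0.31. Endothelial genes were higher in 5 of 9, also adjusted over the list alone (camera adjusted p = 0.019, and adjusted p = 0.45 with an estimated correlation). Members included Flt1, a VEGF receptor, at 1.24 ± 0.22 and Pecam1 at 0.52 ± 0.14. Red blood cell genes were higher in 5 of 6, also adjusted over the list alone (camera adjusted p = 0.0058, and adjusted p = 0.45 with an estimated correlation). Examples were Hbb at 1.86 ± 0.45 and Hbb-b1 at 1.78 ± 0.44, whose reads may be split with near-identical copies. Haemoglobin reads made up 2.05% ± 0.736 of non-mitochondrial reads in RM, 0.784% ± 0.53 in HS, 2.20% ± 1.03 in RM-HS and 1.60% ± 1.39 in Sham. Intercalated cell genes were higher in 2 of 9, also adjusted over the list alone (camera adjusted p = 0.034, and adjusted p = 0.62 with an estimated correlation), namely the transcription factor Foxi1 (0.69 ± 0.16) and Slc4a9 (0.66 ± 0.17). Regulated necrosis and inflammasome genes were higher in 4 of 11, also adjusted over the list alone (camera adjusted p = 0.031, and adjusted p = 0.36 with an estimated correlation), among them Il1b (1.74 ± 0.34) and Nlrp3 (1.03 ± 0.23). Clock genes were higher in 4 and lower in 1 of 15, as adjusted over the list alone (camera adjusted p = 0.025, and adjusted p = 0.36 with an estimated correlation). Among them were Bhlhe40 at 1.39 ± 0.17 and Hlf at 1.57 ± 0.28. Cell cycle genes were lower in 4, or 5 adjusted over the list alone, and higher in 1 of 17 (camera adjusted p = 0.034, and adjusted p = 0.83 with an estimated correlation). Members included the replication factor Mcm2 at -0.57 ± 0.09 and the spindle factor Tpx2 at 1.74 ± 0.48. Tpx2 was reversed among libraries named R (-0.69, limma adjusted p = 0.69), but there RM was RM 1 alone, at 86.8 against 378 to 658 in RM 2 to 6, with the spread taken from other groups. It did not pass with the name letter as covariate (limma adjusted p = 0.06).

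Lists without a camera call in this comparison, but with at least 1 in 4 members passing, were hypoxia with 6 higher and 1 lower of 16, haem and iron with 6 and 3 of 18, p53 targets with 2 and 4 of 12, ferroptosis with 4 and 1 of 11 and fatty acid oxidation with 1 and 4 of 19 (camera adjusted p = 0.052, 0.12, 0.63, 0.62 and 0.51). Adjusted over the list alone, 7 hypoxia, 7 haem and iron and 3 p53 genes were higher and 3 ferroptosis genes lower. Osmotic response genes were higher in 1 and lower in 2 of 7, glucocorticoid response and metallothionein genes in 1 and 2 of 10, liver genes in 1 and 1 of 7, and 1 of 4 adrenal genes was higher (camera adjusted p = 0.58, 0.49, 0.93 and 0.63).

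RM-HS against HS asked what RM adds to HS. Higher in RM-HS were the kinesin Kif5c (5.81 ± 1.66), the granulocyte growth factor Csf3 (4.93 ± 1.01), Slc7a11 (4.76 ± 0.78) and Hmox1 (3.83 ± 0.91). Lower were Colq (-3.42 ± 1.10), the BMP antagonist Grem1 (-3.25 ± 0.71), the cadherin Cdh3 (-2.97 ± 0.41) and Krt20 (-2.86 ± 0.81), which stood at 72.8 ± 48.8 in RM-HS. The groups did not overlap in these 8 genes. Some calls rested on single libraries, namely Kif5c (limma adjusted p = 0.061 without RM-HS 1 and 0.053 without RM-HS 3), Colq (0.19 without RM-HS 1, 0.066 without HS 1 and 0.08 without HS 5, and 0.052 with the name letter as covariate or with array weights) and Krt20 (0.11 without RM-HS 3). In all 3287 genes passed, 1599 higher and 1688 lower, and 879 differed by 2-fold or more. The count was 2020 without RM-HS 3 and 1238 among libraries named R, where Kif5c, Hmox1, Colq, Krt20, Ftl1, Cox4i1 and Ciart did not pass.

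Several gene groups were higher in RM-HS than in HS. Immediate early genes were higher in 12 of 15, or 14 adjusted over the list alone (camera adjusted p = 4.6e-10, and adjusted p = 0.21 with an estimated correlation). Examples were Atf3 at 3.29 ± 0.39 and Zfp36 at 2.12 ± 0.21. Oxidative phosphorylation genes were higher in 13 of 19, or 16 adjusted over the list alone (camera adjusted p = 3.1e-08, and adjusted p = 0.21 with an estimated correlation). Among them was Cox4i1 at 0.47 ± 0.10. Inflammatory cytokines and NF-kB targets were higher in 13 of 17, or 15 adjusted over the list alone (camera adjusted p = 1.2e-07, and adjusted p = 0.21 with an estimated correlation). Members included the cytokine signalling inhibitor Socs3 at 2.58 ± 0.49 and Nfkbia at 1.45 ± 0.16. Glycolysis genes were higher in 9 of 14, or 12 adjusted over the list alone, with Eno1 at 0.74 ± 0.10 and Gpi at 0.70 ± 0.10. This was the only list of any comparison that passed with an estimated correlation (camera adjusted p = 1.4e-07, and adjusted p = 0.022 with an estimated correlation). Cholesterol synthesis was higher in 7 of 13, also adjusted over the list alone (camera adjusted p = 0.00028, and adjusted p = 0.21 with an estimated correlation). Among them was Insig1 at 1.26 ± 0.14. Neutrophil genes were higher in 4 of 9, or 6 adjusted over the list alone (camera adjusted p = 0.0013, and adjusted p = 0.39 with an estimated correlation). Among them was the antimicrobial peptide Camp at 3.46 ± 0.80. NRF2 genes were higher in 5 of 14, or 8 adjusted over the list alone (camera adjusted p = 0.0022, and adjusted p = 0.48 with an estimated correlation). Members included Srxn1 at 1.89 ± 0.35.

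Hypoxia genes were higher in RM-HS in 6 of 16, or 8 adjusted over the list alone (camera adjusted p = 0.0072, and adjusted p = 0.21 with an estimated correlation). Examples were Adm at 2.13 ± 0.26 and Pfkfb3 at 2.0 ± 0.22. The unfolded protein and integrated stress list was higher in 4 of 17, also adjusted over the list alone (camera adjusted p = 0.046, and adjusted p = 0.67 with an estimated correlation). Among them were Ddit3 at 1.48 ± 0.28 and Atf4 at 1.24 ± 0.18. Vasoactive genes were higher in 3 of 13, also adjusted over the list alone (camera adjusted p = 0.014, and adjusted p = 0.21 with an estimated correlation). Members included Bdkrb2 at 2.31 ± 0.35 and Ednra at 1.19 ± 0.26. Red blood cell genes were higher in 5 of 6, also adjusted over the list alone (camera adjusted p = 0.0068, and adjusted p = 0.55 with an estimated correlation). Haem and iron genes were higher in 5, or 6 adjusted over the list alone, and lower in 1, or 2, of 18 (camera adjusted p = 0.041, and adjusted p = 0.21 with an estimated correlation). An example was ferritin light chain, Ftl1, at 0.83 ± 0.20. Clock genes were higher in 3 of 15, also adjusted over the list alone (camera adjusted p = 0.044, and adjusted p = 0.42 with an estimated correlation). Among them were Bhlhe40 at 1.55 ± 0.20 and Ciart at 2.51 ± 0.59. With the name letter as covariate the last lists, haem and iron and the clock, did not pass (camera adjusted p = 0.082 and 0.082). Cell cycle genes were lower in 3 of 17, also adjusted over the list alone (camera adjusted p = 0.005, and adjusted p = 0.67 with an estimated correlation). Members included the spindle motor Kif11 at -1.03 ± 0.18 and Mcm2 at -0.80 ± 0.11. Without a camera call, 3 of 11 ferroptosis genes, 3 of 12 p53 targets and 3 of 19 fatty acid oxidation genes were higher, and 1, 2 and, for osmotic response, 2 of 7 lower (camera adjusted p = 0.34, 0.71, 0.27 and 0.11). Adjusted over the list alone, 4 fatty acid oxidation genes were higher, and 1 ferroptosis, 2 p53 and 3 osmotic response genes lower. Of B and plasma cell genes 1 of 4 was higher, and of 7 liver genes 1 was higher and 1 lower (camera adjusted p = 0.38 and 0.87).

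RM-HS against RM asked what HS adds to RM, and few genes differed. Krt20 was higher in RM-HS (4.64 ± 0.78, limma adjusted p = 0.011), as were Ppp1r32 (2.39 ± 0.35), the macrophage lectin Clec10a (1.57 ± 0.36) and the arginase Arg1 (1.51 ± 0.35). Lower in RM-HS were the urea cycle enzyme Cps1 (-4.01 ± 0.89, 622 ± 603 in RM against 36.9 ± 42.7), the EGF receptor ligand Btc (-2.64 ± 0.35), E-selectin, Sele (-2.35 ± 0.57), and the NK cell receptor Klrb1c (-2.24 ± 0.47). In all 173 genes passed, 63 higher and 110 lower, and 65 differed by 2-fold or more. NRF2 genes were lower in 3 of 14, or 4 adjusted over the list alone (camera adjusted p = 9.9e-05, and adjusted p = 0.78 with an estimated correlation). Examples were the glutathione synthesis subunits Gclm at -0.94 ± 0.19 and Gclc at -0.81 ± 0.17. Cholesterol synthesis was lower in 1 of 13, or 3 adjusted over the list alone (camera adjusted p = 0.0033, and adjusted p = 0.78 with an estimated correlation), the gene being Cyp51 (-0.68 ± 0.14). Endothelial genes were lower in 2 of 9, also adjusted over the list alone (camera adjusted p = 0.049, and adjusted p = 0.78 with an estimated correlation), namely Emcn (-1.34 ± 0.22) and the angiopoietin receptor Tek (-1.52 ± 0.28). The oxidative phosphorylation list lay higher in RM-HS, with a median of 0.15 (camera adjusted p = 9.9e-05, and adjusted p = 0.78 with an estimated correlation), while limma passed 0 of 19 genes, 6 at an unadjusted p under 0.05, edgeR passed 0 and DESeq2 1. Fatty acid oxidation did likewise, with a median of 0.20 (camera adjusted p = 0.0033, and adjusted p = 0.93 with an estimated correlation), limma passing 0 of 19, 6 at an unadjusted p under 0.05, edgeR 0 and DESeq2 1.

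These differences between RM-HS and RM depended on the libraries used. With the name letter as covariate limma passed 0 genes, with 1183 at an unadjusted p under 0.05, and edgeR and DESeq2 were not run that way. Among libraries named R limma also passed 0, with 1082 at an unadjusted p under 0.05, but there RM 1 stands alone for RM and the other groups supply the spread, so that fit decides little. All 173 genes kept their direction with the covariate, their median absolute log2 fold change went from 0.81 to 0.70 and their median SE from 0.16 to 0.21. The count was 21 without RM-HS 1, 24 without RM-HS 3, 480 without RM 1, and 89, 46, 94, 31 and 55 without RM 2, 3, 4, 5 and 6. Of the named genes, Ppp1r32 and Btc passed whichever library was left out. Krt20 did not without RM-HS 1 (4.14, limma adjusted p = 0.061), and Clec10a, Arg1, Cps1, Sele, Klrb1c, Gclm, Gclc, Cyp51, Emcn and Tek did not without RM-HS 1 (limma adjusted p = 0.15, 0.17, 0.13, 0.11, 0.11, 0.054, 0.057, 0.093, 0.06 and 0.09) or without RM-HS 3 (0.17, 0.079, 0.17, 0.18, 0.081, 0.12, 0.089, 0.1, 0.078 and 0.08). Cps1 also missed without any one of RM 2, 3, 4 and 6 (limma adjusted p = 0.06 to 0.071), and Clec10a, Arg1, Sele and Klrb1c without any one of RM 2 to 6 (0.052 to 0.1). Gclm and Cyp51 missed without RM 3, 5 or 6 (limma adjusted p = 0.05 to 0.058) and Gclc without RM 5 (0.059). With the podocyte list mean as covariate the endothelial list did not pass (camera adjusted p = 0.081). Sele, Arg1, Cps1 and Cyp51 also missed in the fit of only RM-HS and RM (limma adjusted p = 0.06, 0.065, 0.077 and 0.079), and Sele and Arg1 under several other settings. Without RM-HS 2 Arg1, Sele, Gclm and Gclc missed (limma adjusted p = 0.11, 0.11, 0.054 and 0.098).

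The departure from additivity asked whether the RM-HS change from Sham differed from the sum of the RM and HS changes on the log2 scale. Havcr1 and Lypd8, which rose in both RM and HS, fell short of the sum. Havcr1 lay -5.62 ± 0.94 from the sum and Lypd8 -5.92 ± 1.18. Also below it were Lexm -5.70 ± 0.74, Csrp3 -6.16 ± 1.27 and Dusp15 -6.57 ± 2.15. Above the sum lay Gjd2 (6.81 ± 1.56), Lrtm2 (6.08 ± 1.21), Fxyd3 (5.88 ± 2.05) and Kif5c (5.73 ± 2.12). All but Kif5c had RM and HS libraries at 0, so their falls could not fully add. In all 5054 genes departed, 2376 above the sum and 2678 below it, and 2133 by 2-fold or more. Where RM-HS matches RM, the departure is the HS change reversed. With the name letter as covariate Gjd2 (3.52), Lrtm2 (3.46), Csrp3 (-5.49) and Lypd8 (-5.88) missed (limma adjusted p = 0.29, 0.17, 0.081 and 0.052), as did Fxyd3, Kif5c and Dusp15. Of the genes named here and below, those that passed with that covariate were Havcr1, Lexm, Itgb6, Acsl4, Insig1, Cldn10, Sgk1, Myc and Dnajb9, and the others had limma adjusted p of 0.052 to 0.66. Fxyd3, Kif5c and Dusp15 also depended on single libraries. Fxyd3 missed without any one of 12 libraries (limma adjusted p = 0.05 to 0.099), missed with Sham 1 and Sham 6 alone (4.43, limma adjusted p = 0.22) and reversed with the name letter as covariate (-1.35). Kif5c missed without any one of 15 libraries (limma adjusted p = 0.05 to 0.087). Dusp15 missed without RM-HS 2 or RM-HS 3 (limma adjusted p = 0.099 and 0.1) and with Sham 1 and Sham 6 alone (-3.15, limma adjusted p = 0.28). Neither Fxyd3 nor Dusp15 passed by edgeR or DESeq2, or with the podocyte list mean as covariate, under which Wt1, Ifi27 and Vldlr did not pass either (limma adjusted p = 0.091, 0.062 and 0.065).

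Injury markers lay below the sum in 7 of 19, or 9 adjusted over the list alone (camera adjusted p = 0.0037, and adjusted p = 0.71 with an estimated correlation). Among them was Itgb6 at -1.18 ± 0.16. Immediate early genes lay below it in 8 of 15, also adjusted over the list alone (camera adjusted p = 0.0046, and adjusted p = 0.71 with an estimated correlation). Members included Myc at -2.56 ± 0.33 and Klf6 at -2.18 ± 0.36. Cholesterol synthesis did in 8 of 13, or 9 adjusted over the list alone (camera adjusted p = 0.0046, and adjusted p = 0.7 with an estimated correlation). An example was Insig1 at -1.32 ± 0.18. The unfolded protein and integrated stress list did in 5 of 17, or 7 adjusted over the list alone (camera adjusted p = 0.0046, and adjusted p = 0.71 with an estimated correlation). Among them were Dnajb9 at -1.75 ± 0.30 and Vldlr at -0.87 ± 0.21. Heat shock did in 4 of 10, or 6 adjusted over the list alone (camera adjusted p = 0.034, and adjusted p = 0.84 with an estimated correlation). Members included Hsp90aa1 at -2.23 ± 0.46. The osmotic response did in 4 of 7, or 5 adjusted over the list alone (camera adjusted p = 0.03, and adjusted p = 0.7 with an estimated correlation). Examples were the kinase Sgk1 at -1.78 ± 0.20 and Hspa4l at -1.16 ± 0.21. Ferroptosis genes lay below in 5, or 6 adjusted over the list alone, and above in 1 of 11 (camera adjusted p = 0.046, and adjusted p = 0.7 with an estimated correlation). Among them were Slc7a11 at -3.51 ± 0.99 and Acsl4 at -1.42 ± 0.19. Podocyte genes lay below in 4 of 8, or 7 adjusted over the list alone (camera adjusted p = 0.028, and adjusted p = 0.84 with an estimated correlation). Members included Wt1 at -2.09 ± 0.53, and this list moved with the low Sham libraries (camera adjusted p = 0.31 with Sham 1 and Sham 6 alone).

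Segment lists that were lower in RM or HS lay above the sum. Thick ascending limb genes did in 7 of 10, or 8 adjusted over the list alone (camera adjusted p = 0.0022, and adjusted p = 0.7 with an estimated correlation). Examples were uromodulin, Umod (GSRG0004479, rn6 chromosome 1, 189186023 to 189199382), at 1.73 ± 0.32 and Cldn10 at 1.65 ± 0.22. Umod stood at 191000 ± 35100 in Sham, 92800 ± 30000 in RM, 83300 ± 20800 in HS and 128000 ± 8340 in RM-HS. Collecting duct principal cell genes lay above in 3 of 10, also adjusted over the list alone (camera adjusted p = 0.011, and adjusted p = 0.71 with an estimated correlation). Among them were Aqp3 at 1.68 ± 0.39 and Hsd11b2 at 1.63 ± 0.35. Intercalated cell genes did in 4 of 9, or 6 adjusted over the list alone (camera adjusted p = 0.013, and adjusted p = 0.71 with an estimated correlation). Members included Slc4a1 at 2.04 ± 0.40 and Atp6v1b1 at 1.43 ± 0.34. With Sham 1 and Sham 6 alone the collecting duct and intercalated lists did not pass (camera adjusted p = 0.08 and 0.13), nor did ferroptosis (0.12) or the gene Aqp3 (1.32, limma adjusted p = 0.051). Oxidative phosphorylation genes lay above the sum in 12 of 19, also adjusted over the list alone (camera adjusted p = 0.00016, and adjusted p = 0.71 with an estimated correlation). Examples were Ndufv1 at 0.68 ± 0.11 and Uqcrc1 at 0.54 ± 0.12. Interferon response genes did in 4 of 15, also adjusted over the list alone (camera adjusted p = 0.028, and adjusted p = 0.84 with an estimated correlation). Among them were Usp18 at 2.32 ± 0.59 and Ifi27 at 1.28 ± 0.37. With the name letter as covariate the collecting duct, interferon and heat shock lists did not pass (camera adjusted p = 0.069, 0.07 and 0.062).

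Without a camera call, 6 of 14 NRF2 genes, 6 of 12 p53 targets, 5 of 16 hypoxia genes and 5 of 18 proximal tubule genes lay below the sum, and 2, 1 and 2 of the last 3 above it. Adjusted over the list alone, 1 NRF2 and 2 hypoxia genes lay above. Of 19 fatty acid oxidation genes 7 lay above the sum (camera adjusted p = 0.056, 0.13, 0.62, 0.45 and 0.056). Above and below were 2 and 3 of 18 haem and iron genes, 1 and 2 of 11 regulated necrosis genes and 2 (or 3 adjusted over the list alone) and 1 of 9 endothelial genes. Below was 1 of 4 genes in the distal convoluted tubule and adrenal lists each (camera adjusted p = 0.91, 0.89, 0.81, 0.43 and 0.91). The count of departing genes was 3151 with Sham 1 and Sham 6 alone, 2818 of them the same genes in the same direction, and 9 of 13 lists kept their camera call. With the podocyte list mean as covariate 8 of 13 did, and ferroptosis, collecting duct, intercalated cell, podocyte and interferon lists did not pass (camera adjusted p = 0.2, 0.056, 0.068, 0.93 and 0.073). It was 617 with the name letter as covariate and 0 with limma among libraries named R, where 2055 had an unadjusted p under 0.05. Upper quartile scaling, with a shift of 0.10 log2 in the median, gave 2946 above the sum and 2208 below it.

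**Figure D3:**
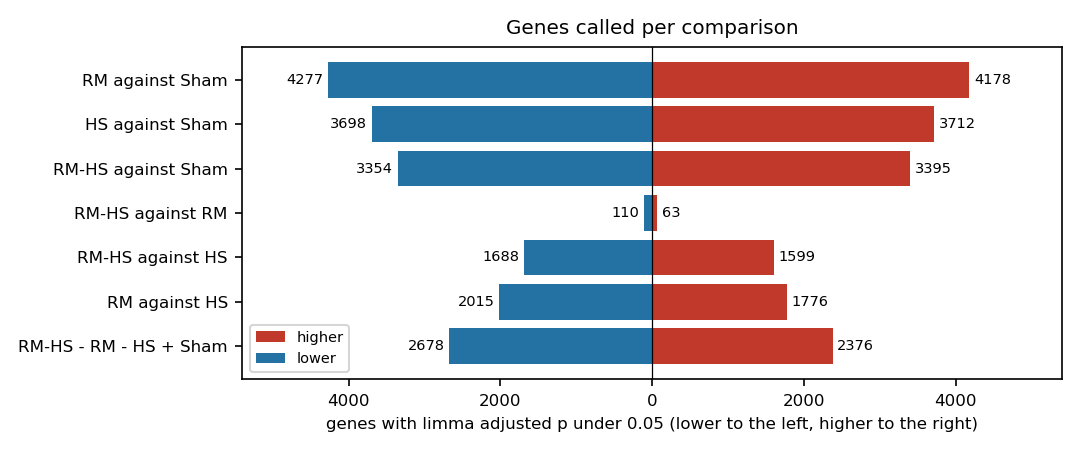
Numbers of genes with a limma adjusted p under 0.05 in each of the 7 comparisons, higher to the right and lower to the left of 0 on the x axis. RM against Sham has the most, 4178 higher and 4277 lower, and RM-HS against RM the fewest, 63 and 110.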

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

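The tests in this part were written after the results they measure were seen, except the test of name letters between RM-HS and RM. The departure from additivity stands here because, by a direct test, the RM-HS change differed from the RM and HS sum in 5054 genes. The other results are genes with 1 library far from the others of its group. Of 87 gene and group pairs over 29 genes, 20 were, but the rate by chance was not tested.

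The first pattern was that 7 early proximal tubule genes were higher in RM, HS and RM-HS than in Sham. A smaller share of cortex in Sham 2 to 5 would lower podocyte genes alike, but the early proximal tubule genes lay lower than the podocyte genes by at least 2.86 log2 (SD of that difference over the 14 RM, HS and RM-HS libraries 0.38). Against Sham 1 and Sham 6 at most 19.1% of the median log2 fold change remained, but these controls were chosen as the highest in the same genes, so this decides nothing about a response shared by RM, HS and RM-HS, which stays open. A batch of the libraries whose names carry numbers 30 to 35 cannot be told apart from a state of those samples, since 0 libraries of RM, HS or RM-HS carry such numbers. What set Sham 2 to 5 apart stays open, and kidney region other than cortex share and the handling of those samples were not tested.

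The second pattern was the departure from additivity. If the makeup of Sham 2 to 5 were the whole cause, the departures would vanish against Sham 1 and Sham 6, but over the 5054 genes their slope on the original ones was 0.93, with 100% in the same direction. If a difference between libraries named R and S were the whole cause, they would vanish with the letter as covariate, but the slope was 0.83, with 99.9% in the same direction. Fewer genes passed in these fits, whose median SE was 1.19 and 1.37 times as large. A limit reached in RM or HS alone was not tested, nor were other scales of measurement. RM-HS differed from HS in 3287 genes and from RM in 173.

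The third pattern was the genes that differ between RM-HS and RM, where of RM only RM 1 is named R, as are all RM-HS and Sham libraries. In 480 genes that passed without RM 1, that library lay 0.63 of the way from RM 2 to 6 to RM-HS, and RM 2 to 6 lay between -0.09 and 0.08. In a control added later, each of RM 2 to 6 left out in turn lay between -0.09 and 0.15 in the genes that passed without it. A difference between libraries named R and S predicts this and RM 1 lying towards Sham, 0.36 of the way (others -0.12 to 0.06). A milder change in RM 1 predicts the latter too and remains open. The letter itself passed for 1 gene by limma, with 973 at an unadjusted p under 0.05.

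Chance was examined by other splits of the same libraries. For RM against Sham 1 of 100 splits gave as many genes (8455, highest other 2357), for HS against Sham 1 of 100 (7410, highest other 4796), and for RM-HS against Sham 1 of 84 (6749, highest other 1439). For RM-HS against HS it was 1 of 56 (3287, highest other 159), and for RM against HS 1 of 100 (3791, highest other 2057), so chance can be excluded in these 5 over splits that ignore the name letter. For additivity it was 1 of 100 (5054, highest other 1), but these splits move all 20 libraries, which also widens the spread within groups, so they decide little. With the letter as covariate RM against Sham gave 4551 genes and additivity 617. For RM-HS against RM 2 of 84 splits gave as many (173, highest other 218), and chance can again be excluded only over splits that ignore the letter. The other split set RM-HS 2, RM-HS 3 and RM 1, all named R, against the rest. The 4 sets of 3 libraries named R gave 173, 218, 93 and 0 genes by limma, too few sets for a share under 0.05, and with the letter as covariate limma passed 0 genes (1183 at an unadjusted p under 0.05).

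Among Sham libraries, Sham 2 was far from the others in Lypd8 (5.16, others 0 to 0.953), Fosl1 (42.1, others 3.04 to 10.6), Fgb (858, others 44.1 to 184), Fgg (310, others 15.1 to 109) and Atf3 (363, others 115 to 194). Sham 6 was in Hmox1 (12900, others 400 to 500) and Htr5b (190, others 68.6 to 103). RM 1 was in Hmox1 (109000, others 158000 to 172000), Tril (48.7, others 10.1 to 22.2), Lrtm2 (12.7, others 0 to 3.8) and Tnni3k (136, others 0 to 20.3). RM 3 was in Rd3l (3.04, others 0), Dok7 (18.2, others 2.08 to 6.66) and Spp1 (222000, others 43800 to 103000), RM 5 in Htr5b (43.3, others 6.35 to 12.5) and RM 6 in Lypd8 (1370, others 109 to 521). HS 1 was in Krt20 (1050, others 275 to 417), HS 2 in Hmox1 (36000, others 2470 to 4970), HS 3 in Lypd8 (838, others 26.6 to 257) and HS 5 in Smad9 (94.5, others 13.5 to 23.3).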

How the results depend on the processing

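Controls Sham 1 and Sham 6 alone and the podocyte list mean as covariate were chosen after seeing the data, and the other alternatives before. Counts of passing genes stayed within 1.5 times under each alternative not named here. In RM against Sham they were 4551 with the name letter as covariate, 782 among libraries named R (where RM 1 is the only RM library, as in every such fit), 5250 with Sham 1 and Sham 6 and 5596 with the podocyte covariate. With Sham 1 and Sham 6, HS against Sham gave 4105 and RM-HS against Sham 4347. In RM-HS against RM limma gave 0 with the letter (1183 at an unadjusted p under 0.05), 0 among libraries named R (1082), 333 with array weights and 79 with only the groups compared, and DESeq2 gave 505. Among libraries named R, RM-HS against HS gave 1238 and RM against HS 208. Additivity gave 617 with the letter, 0 by limma among libraries named R (2055 at an unadjusted p under 0.05), 3151 with Sham 1 and Sham 6 and 3333 with the podocyte covariate. Fits of libraries named R hold fewer libraries, and in the 173 genes of RM-HS against RM the median absolute log2 fold change went from 0.81 to 0.61 as the median SE went from 0.16 to 0.28. The cause was not tested for these counts. With an estimated correlation camera passed 0, 0, 0, 0, 1, 0 and 0 lists for RM, HS and RM-HS against Sham, RM-HS against RM, RM-HS against HS, RM against HS and additivity (unadjusted p under 0.05: 6, 2, 6, 1, 8, 6 and 2).

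Leaving out 1 library gave, in that order, 7823 to 8538, 6652 to 7506, 5049 to 6839, 21 to 480, 2020 to 3288, 3027 to 3716 and 3992 to 5520 genes. Over 1.5 times away were 2020 without RM-HS 3 in RM-HS against HS, and in RM-HS against RM 21 and 24 without RM-HS 1 and 3, 480 without RM 1, and 89, 46, 94, 31 and 55 without RM 2 to 6. Of 252 named gene results 147 kept direction and side of the threshold under every alternative, 105 changed under at least 1, and 24 did so when 1 library was left out. Tpx2 in RM against HS reversed among libraries named R (-0.69), where RM is RM 1 alone, and Fxyd3 in additivity reversed with the letter (-1.35) and among libraries named R (-1.3), and the cause was not tested. No paired analysis was possible because replicate numbers only follow the order in which the samples are listed.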
